A study of Mus musculus with 2 samples.

How the data were processed

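H3K4me2 ChIP-seq of midbrain tissue from mouse embryos at day 16.5 was represented by 2 biological replicates, which the labels give as separate tissue pools. Their 4 deposited peak lists were used. Per the deposited file lists, 1 list per replicate was made from that replicate's filtered alignments and further files of no stated type, a pooled list from the alignments of both replicates, and a replicated list from the lists of both replicates and the pooled list. The labels mention a possible control experiment, which was not analysed here. Coordinates are on mm10, per the labels. The aligner, the peak caller and their settings were not given in the sources used here.

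The deposited lists have the narrowPeak layout, from which the meaning of the columns was taken. The authors' enrichment of each peak is a ratio given as deposited. The sources used here do not state what it is relative to, nor whether the control experiment entered it. The authors' -log10 p of each peak was used only to rank peaks and the deposited -log10 q only with the replicate lists, for 1 added alternative and for the shares of peaks above a q-value of 0.05. The summit offset in bases from the peak start was used to place peaks. Each list carries enrichments of its own, so these values served to describe, rank or filter peaks within a list, and as ranks and ratios in the comparison of the replicates. In the replicate lists, 3.04% of replicate 1 peaks and 1.90% of replicate 2 peaks had a q-value above 0.05. The lists hold no read counts, so the depth per sample is unknown and no interval that needs it is given. Exact binomial 95% intervals of shares of peaks cover counting error only.

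Peaks on the 21 chromosomes were analysed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and bedtools 2.31.1. The annotation was GENCODE release M21 for GRCm38, the assembly of mm10. A gene's TSSs were the starts of its transcripts in the GENCODE basic set. There were 21938 protein-coding genes with a median of 2 TSSs. A promoter had a peak where a peak overlapped the TSS ± 1 kb of at least 1 TSS. Breadth was the number of bases covered by peaks within 5 kb of the TSS with the most covered bases, as the mean of both replicates. A promoter was CpG-rich where the 500 bases on either side of a TSS had at least 55% G and C and an observed to expected CpG ratio of at least 0.6. Summits were assigned in the order promoter (within 1 kb of any TSS), exon, intron and intergenic. A peak counted as shared when at least 50% of it was covered by the other list. Random placements (100 draws) kept the chromosome and width of each peak and avoided assembly gaps.

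The 18 gene lists (housekeeping, midbrain patterning, dopaminergic neuron, neurotransmitter identity, pan-neuronal, neural progenitor, forebrain factors, Hox, oligodendrocyte lineage, astrocyte, microglia, endothelial and mural, erythroid, muscle, liver, epidermal, germline, immediate-early and stress) and the olfactory receptors were fixed before the data were examined, as were the tests and the alternatives except those named as added. Of the listed symbols, 1 erythroid gene (Ahsp) had no match among the annotated protein-coding genes. No gene stood in more than 1 list. Occupancy was compared with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over 19 lists. Such tests treat genes as the units and describe these pooled tissues, and genes of a cluster, such as Hox or olfactory receptor genes, are not independent. Breadth was placed as a percentile among 10000 random lists of the same size and promoter CpG decile. Regional factors were compared by a permutation test of the difference of medians with 100000 permutations and adjustment over 2 comparisons.

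Genes were named by a rule. For each list it took the 3 members with the most covered bases and up to 2 members, in alphabetical order, without a promoter peak in either replicate. It further took the genes with a TSS in the 10 broadest domains, and the protein-coding genes nearest to the 10 replicated peaks of highest enrichment within 1 kb of a TSS and more than 5 kb from any TSS. Domains joined replicated peaks across gaps of up to 1 kb.

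The functions were tested on simulated data. Covered bases equalled those of bedtools coverage in all of 2000 windows. With 70.0% of 51868 replicate 1 peaks kept in place, 70.1% were called shared. Of 500 random gene lists, 3.8% had an unadjusted p under 0.05 for occupancy, and of 100 lists of 20 genes with 95% occupancy against 66% elsewhere, 36% were called, so a list of this size that is not called may still differ. When peaks were placed at the promoters of chosen genes, 7.13% of the genes without one were called through a neighbour. For 9691 isolated TSSs with 65.3% of summits placed downstream, 65.3% were recovered.

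The alternatives were other windows, the pooled list, each replicate alone, an enrichment of at least 4, other overlap and merging rules, 1 TSS per gene and unmatched random lists. Added after seeing the data were the comprehensive TSS set, a peak required in both replicates, a q-value of at most 0.05, the breadth at the outermost TSS, and the peak numbers, covered bases and ranks of the strongest peaks in each replicate alone. Peaks on unlocalized and unplaced scaffolds were left out of all comparisons, since genes were assigned on the 21 chromosomes only.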

Results

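Dimethylation of lysine 4 on histone H3 (H3K4me2), a mark found around active and poised promoters and enhancers, was mapped by ChIP-seq in the midbrain of B6NCrl mouse embryos at embryonic day 16.5. All samples belonged to 1 group with 2 biological replicates, each a pool of embryos of both sexes. The pool of replicate 2 came from 37 embryos, and the size of the other pool was not given in the sources used here. The labels named no treatment and no second tissue, so the comparisons below are between replicates, between parts of the genome and between groups of genes. Sequencing depth was unknown, since the peak lists carried no read counts.

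On the 21 chromosomes (autosomes, X and Y), replicate 1 had 51868 peaks and replicate 2 had 52216, a mean of 52042 ± 246 (SD, n = 2). The peaks covered 47.6 Mb in replicate 1 and 54.9 Mb in replicate 2, or 1.94% ± 0.195 (SD, n = 2) of the sequenced genome. The median peak was 572 bases wide in replicate 1 and 628 bases in replicate 2. The list that the authors called on both replicates together held 48144 peaks. Their list of replicated peaks held 42076 peaks over 51.2 Mb, with a median width of 843 bases, and each of the 42076 had the coordinates of a peak in the pooled list.

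Most H3K4me2 sites of one replicate were found in the other. At least 50% of the bases were covered by the other list for 84.4% of replicate 1 peaks and for 68.9% of replicate 2 peaks. Random placements of the other list gave at most 2.26% and 1.85% in 100 draws. The Jaccard index of covered bases was 0.766, against at most 0.0112 for random placements. The peaks not found in the other replicate were the weaker ones. Among the 25% of replicate 2 peaks with the lowest enrichment, 76.8% were not found in replicate 1, against 0.0536% of the strongest 25%. For replicate 1 the shares not found were 48.2% in the lowest 25% and 0% in the highest. Only 11.2% of the unshared replicate 2 peaks had their summit at a promoter, compared with 47.4% of the shared ones. Of the 42076 replicated peaks, 37535 (89.2%) were covered in both replicates, 3794 in replicate 2 only, 710 in replicate 1 only and 37 in neither.

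Peak strength varied in parallel between the replicates. Across 39322 pooled peaks matched in both lists, Spearman's rho of the log2 enrichment was 0.902 and Pearson's r was 0.913. These are correlations across peaks, which are not independent replicates, and no p-value was computed. The enrichment, a ratio that the authors' peak lists give for each peak, was higher in replicate 2, with a median ratio of 1.34 to replicate 1.

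**Figure D1:**
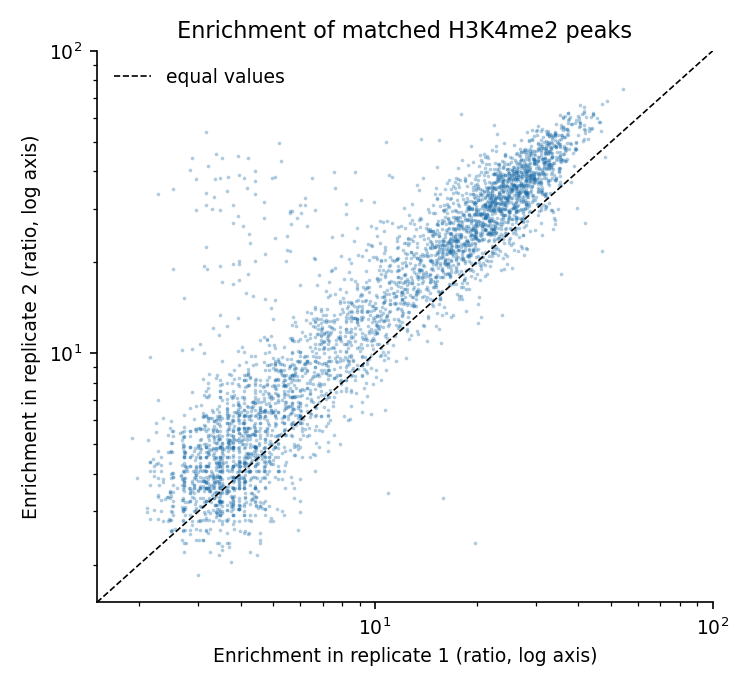
Enrichment (ratio, log axes) of matched peaks in replicate 1 (x axis) and replicate 2 (y axis), 1 point per pooled peak for a random draw from the 39322 matched peaks. Most points lie above the dashed line of equal values, as the median ratio of 1.34 states.

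H3K4me2 was concentrated at promoters. The summit lay within 1 kb of an annotated transcription start site (TSS) for 17959 replicated peaks, or 42.7%, which was 9.46 times the 4.51% ± 0.0940 (SD, 100 draws) of random placements. In the single replicates the promoter share was 37.4% ± 1.80 (SD, n = 2). Exons held 4.84% of the summits, introns 31.9% and intergenic sequence 20.6%. The corresponding random means were 3.11%, 42.2% and 50.1%, so exons were above and introns and intergenic sequence below the range of all 100 placements. Promoter peaks were the strongest and widest, with a median enrichment of 24.4 and a median width of 1429 bases, against 4.92 and 530 bases for intronic peaks and 5.57 and 557 bases for intergenic peaks. A further distance criterion showed that 15038 replicated peaks (35.7%) had their summit more than 5 kb from any TSS of the basic set. With a promoter window of 500 bases the promoter share fell to 27.0%.

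**Figure D2:**
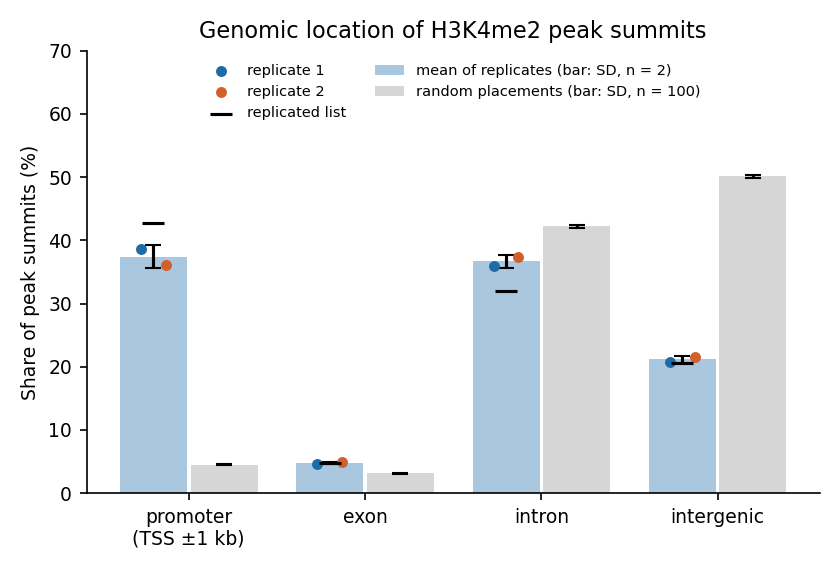
Share of peak summits (%) in promoters (within 1 kb of a TSS), exons, introns and intergenic sequence. Blue bars are the mean of the replicates with its SD (n = 2), points the single replicates, black dashes the replicated list and grey bars the mean and SD of 100 random placements; the promoter bar of 37.4% stands above the random 4.51%.

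The replicated peaks of highest enrichment near a TSS lay at genes of several kinds. The strongest spanned chromosome 18, positions 34859108 to 34863412 (mm10), at Egr1, an activity-induced zinc-finger transcription factor, with an enrichment of 69.7 and its summit 188 bases downstream of the TSS. It was followed by peaks at Adamts3 (68.5), Col27a1 (68.4), Ticrr (67.4), Adgrg6 (66.5), Tcf7l1 (64.9), Gjb2 (64.0), Fam78a (63.7), Ank3 (63.0) and Emilin2 (62.9). Tcf7l1 encodes a transcription factor of the WNT pathway, Gjb2 a connexin, and Ank3 the ankyrin of the axon initial segment. The Tcf7l1 peak, at rank 7 of all replicated peaks, had rank 6 by the enrichment in replicate 2 and rank 61 by that in replicate 1.

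Among peaks more than 5 kb from any TSS, the strongest lay in an intron of Rreb1 on chromosome 13, positions 37777779 to 37779599, with an enrichment of 72.9, the highest of the replicated list. Its summit was 47.4 kb upstream of the nearest protein-coding TSS of the basic set, that of Rreb1 itself, yet inside the annotated Rreb1 gene. A TSS outside the basic set may therefore lie nearer, since distal peaks were not checked against the comprehensive TSS set. Other strong distal peaks were intronic in Phactr1 (53.6), Fgf12 (53.4), Tacc1 (51.8) and Cdh23 (51.7). The Fgf12 and Tacc1 summits also lay inside the gene but upstream of its nearest basic-set TSS, by 118 kb and 39.2 kb, so the same limit applies. The peaks nearest to Clba1 (57.4) and Ccdc83 (52.1) lay in introns of their neighbours Ahnak2 and Sytl2. Intergenic peaks had 1700016H13Rik (57.3), Akna (56.8) and Bhlha9 (56.7) as their nearest protein-coding genes, at 36.3 kb, 6.99 kb and 49.7 kb.

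Promoters of 14418 of 21938 protein-coding genes (65.7%) overlapped a replicated peak within 1 kb of an annotated TSS. The share was 66.1% ± 0.471 (SD, n = 2) in the single replicates, and 296 genes (1.35%) had a promoter peak in one replicate only. Promoters with and without CpG-rich sequence differed in the share with a peak. Of 9565 genes with a CpG-rich promoter, 9457 (98.9%) had a peak, compared with 4961 of 12373 other genes (40.1%). The odds ratio was 131 (95% interval 108 to 159), and the two-sided p-value of Fisher's exact test was too small for the computer's number range. Another protein-coding gene had a TSS within 1 kb for 12.3% of the genes, and a peak between such neighbours was counted for both.

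Promoter H3K4me2 was present at nearly all genes of 6 lists. All 20 pan-neuronal genes had a replicated promoter peak, as did all 20 neural progenitor genes (Fisher's exact test, adjusted p = 0.00110 for each list). The midbrain patterning factors had a peak at 28 of 29 promoters (Fisher's exact test, adjusted p = 0.000360), the forebrain transcription factors at 19 of 20 (adjusted p = 0.00652), the housekeeping genes at 27 of 27 (adjusted p = 0.000105) and the immediate-early and stress genes at 13 of 13 (adjusted p = 0.00929). These 6 of the 19 lists exceeded the remaining protein-coding genes, of which about 65.7% had a peak, in two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 19 lists. Against random lists matched on promoter CpG content, the pan-neuronal count of the replicated list was above the central 95% (percentile 99.4, with a mean of 85.7% in matched lists). The housekeeping, midbrain patterning, forebrain and immediate-early and stress counts were at percentiles 78.3, 66.1, 70.5 and 77.7. The neural progenitor count was also within the central 95%, with a mean of 93.7% in matched lists. Midbrain patterning factors stood at percentile 91.0 with replicate 2 alone, where all 29 had a peak. The housekeeping, neural progenitor and immediate-early and stress counts were the highest possible, since every promoter had a peak, and matched lists reached that count too. Such ties kept these counts within the central 95%, so their place there does not show a lack of excess. The pan-neuronal count was also the highest possible, but fewer matched lists reached it. The midbrain patterning count with replicate 2 alone has the same ceiling. The forebrain count was above the central 95% with replicate 2 alone (percentile 98.4) and with a window of 2 kb (percentile 98.0). With only the outermost TSS of each gene, 12 of 13 immediate-early and stress genes had a peak and the call ended (Fisher's exact test, adjusted p = 0.0568).

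Within these lists H3K4me2 often spread far from the TSS. In the 10001-base window centred on the TSS, Gata3, a factor of GABAergic midbrain neurons (TSS at chromosome 2, position 9878600), was covered over all 10001 bases in both replicates. Lhx1 (chromosome 11, position 84525535) was covered over 9975 ± 36.8 bases (SD, n = 2) and Meis2, a homeodomain factor of the dorsal midbrain (chromosome 2, position 116064512), over 9885 ± 165 bases. Among pan-neuronal genes the most covered were Elavl4, an RNA-binding protein of neurons, with 7951 ± 946 bases, Tubb3, the neuronal tubulin, with 7338 ± 24.7 bases, and Ina, a neurofilament-type protein, with 6622 ± 34.6 bases. Sox2, the transcription factor of neural stem cells, had 7831 ± 27.6 bases, the Notch ligand gene Dll1 had 7613 ± 34.6 bases and Sox1 had 6976 ± 1144 bases. The forebrain list was led by Lhx2 with 9885 ± 164 bases, Emx2 with 8805 ± 725 bases and Six3 with 8502 ± 969 bases. Tubb5, Polr2a and Ubc led the housekeeping genes with 6999 ± 931, 5399 ± 397 and 5065 ± 587 bases. Ier2, Jun and Dusp1 led the immediate-early and stress genes with 6431 ± 60.1, 5744 ± 692 and 5226 ± 76.4 bases (all SD, n = 2).

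Neurotransmitter and glial lists were mixed. Genes of dopaminergic neurons had a promoter peak at 11 of 14 members (adjusted p = 0.482), neurotransmitter identity genes at 14 of 16 (adjusted p = 0.0892), oligodendrocyte lineage genes at 9 of 14 (adjusted p = 1), astrocyte genes at 8 of 11 (adjusted p = 0.848) and endothelial and mural genes at 9 of 14 (adjusted p = 1), and none of these lists differed from other genes in the Fisher's exact test. Sox6, Kcnj6 and Nr4a2, the last a factor required for dopaminergic neurons, had 6530 ± 439, 5564 ± 23.3 and 5307 ± 86.3 covered bases (SD, n = 2), whereas Aldh1a1 and Ddc had no promoter peak in either replicate. With the comprehensive TSS set, chosen after seeing the data, the share of dopaminergic genes with a peak rose from 78.6% to 85.7%. An absence in this list can therefore depend on the TSS set, and which gene gained a peak is not given here. The GABA synthesis and vesicular transport genes Gad1 and Slc32a1 had 9554 ± 430 and 9530 ± 19.1 bases, and Slc17a6, the vesicular glutamate transporter, had 7966 ± 358 bases. The noradrenergic gene Dbh and the histaminergic gene Hdc had no promoter peak. Olig2, Nkx2-2 and Cnp led the oligodendrocyte lineage with 5665 ± 1719, 5442 ± 1971 and 3285 ± 904 bases, while the myelin genes Mag and Mobp had no promoter peak. In the astrocyte list, Slc1a2, Sparcl1 and Fgfr3 had 6578 ± 2.83, 4726 ± 969 and 4549 ± 831 bases, and Agt and Gfap had no promoter peak. Kdr, Sox18 and Pdgfrb had 2538 ± 446, 2507 ± 419 and 2495 ± 419 bases, and Cdh5 and Emcn had no promoter peak.

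Markers of microglia, which are brain cells, and of several other tissues had few promoter peaks. The peaks were called on tissue pools, so a missing peak does not show that a cell type within the tissue lacked the mark. A replicated peak was present at 2 of 15 microglial promoters (Fisher's exact test, adjusted p = 0.000167), 4 of 16 muscle promoters (adjusted p = 0.00222), 1 of 14 liver promoters (adjusted p = 8.13e-05), 2 of 10 epidermal promoters (adjusted p = 0.00657), 3 of 18 germline promoters (adjusted p = 0.000128) and 4 of 1135 olfactory receptor promoters (0.352%, with a p-value too small for the computer's number range). Among random lists matched on promoter CpG content, the germline and olfactory receptor counts were at percentile 0, and muscle and liver at 1.31 and 1.94. The muscle count was at 16.9 with replicate 2 and the liver count at 6.27 with a window of 2 kb. Microglial and epidermal counts, at percentiles 10.4 and 8.6, were within the central 95%. The erythroid list, with 3 of 10, did not pass the threshold (Fisher's exact test, adjusted p = 0.0517) but passed it in 4 of the alternative settings, with the lowest adjusted p of 0.00697 for a window of 500 bases. Among random lists matched on promoter CpG content, which had a mean of 12.0%, the erythroid count was not low (percentile 95.6). The marker genes without a peak included Aif1 and C1qa of microglia, Alas2 and Gata1 of red cell precursors, Acta1 and Ckm of muscle, Afp and Alb of liver, Dsg1a and Flg of epidermis, and Ddx4 and Figla of the germ line, as well as Olfr1 and Olfr10. Some members of these lists did carry the mark. Hexb, a lysosomal enzyme, had a promoter peak and 1312 ± 412 covered bases (SD, n = 2). Mylpf and the muscle regulator Myod1 had 3813 ± 213 and 1794 ± 151 bases, Epor, Klf1 and Gypa had 1642 ± 89.1, 1467 ± 111 and 799.5 ± 33.2 bases, Lor and Krt10 had 2830 ± 38.9 and 1955 ± 255 bases, Boll had 980.0 ± 127 bases, Apob had 309.5 ± 31.8 bases and Olfr94 had 1587 ± 106 bases. Cd68 (3495 ± 547), Acta1 (2213 ± 12.7), Tnp2 (2882 ± 18.4), Gdf9 (2135 ± 52.3), Apoa1 (1547 ± 206), Olfr1344 (1458 ± 314), Sfn (1196 ± 48.1), Olfr750 (873 ± 7.07), C1qa (663.5 ± 26.2) and Afp (128.5 ± 182) had covered bases within 5 kb but no peak within 1 kb of a TSS.

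Hox genes, which pattern the hindbrain and the trunk, had few and narrow peaks. A replicated peak was present at 16 of 39 Hox promoters (41.0%), fewer than for other protein-coding genes (adjusted p = 0.00372, Fisher's exact test). The call ended with the peaks of replicate 2 alone, where 21 of 39 had a peak (Fisher's exact test, adjusted p = 0.158), and with a window of 2 kb (adjusted p = 0.158). Of the 23 CpG-rich Hox promoters 11 had a peak. The most covered were Hoxa1 (chromosome 6, TSS at 52158317), Hoxd1 (chromosome 2, TSS at 74762980) and Hoxa7 (chromosome 6, TSS at 52217452), with 1149 ± 245, 1134 ± 245 and 1049 ± 67.9 bases (SD, n = 2). Hoxa10 and Hoxa11 had no covered base within 5 kb in either replicate.

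The lists also differed in the breadth of the mark. The median number of covered bases within 5 kb of the TSS was 5476 for neural progenitor genes and 5387 for pan-neuronal genes, where random lists matched on promoter CpG content had medians of 2464 and 2134. Both stood at the 100th percentile of 10000 random lists, as did midbrain patterning factors with 4020 bases and housekeeping genes with 3712 bases. Immediate-early and stress genes (4308 bases, percentile 99.96), astrocyte genes (3213 bases, percentile 99.9), neurotransmitter identity genes (2682 bases, percentile 98.9) and forebrain factors (3159 bases, percentile 98.8) were also above the central 95%, which made 8 of 19 lists. The Hox median of 377.5 bases was below all 10000 random lists, and the germline median was 0 bases (percentile 0.165). The other 9 lists lay within the central 95%. Of these, dopaminergic, endothelial and mural, and oligodendrocyte genes had medians of 1912, 1446 and 1258 bases (percentiles 50.7, 44.7 and 13.4) and muscle genes 50.75 bases (percentile 27.2; 0 bases in replicate 1 and 101.5 in replicate 2). Microglial, erythroid, liver, epidermal and olfactory receptor genes had medians of 0 bases (percentiles 44.9, 47.9, 34.6, 29.5 and 50). Their CpG-matched random lists also had a median of 0 bases. These percentiles are therefore ties at the floor, and a call below the central 95% was not possible for these lists. With a window of 2 kb, 4 lists were above the central 95%, and the housekeeping, midbrain patterning, neurotransmitter and forebrain lists were no longer among them. The neurotransmitter call also ended with a window of 10 kb (percentile 96.4), unmatched random lists (percentile 96.7) and an enrichment of at least 4 (percentile 95.7), and the forebrain call ended with an enrichment of at least 4 (percentile 88.3).

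**Figure D3:**
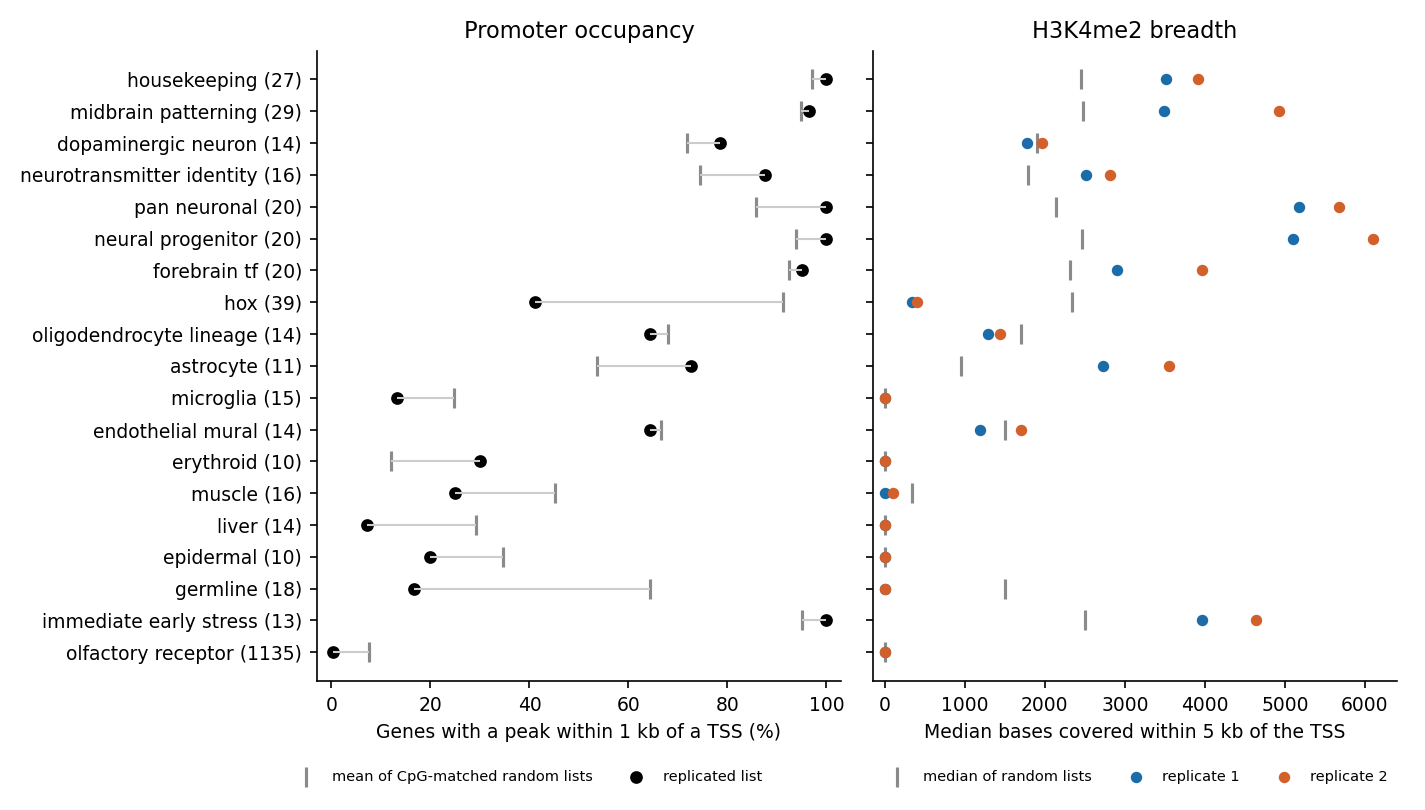
Left, share of each list's genes (%) with a replicated peak within 1 kb of a TSS (black points) and the mean of CpG-matched random lists (grey ticks). Right, median covered bases within 5 kb of the TSS in replicate 1 (blue) and replicate 2 (orange) and the median of random lists (grey ticks). Numbers of genes follow the list names, and the Hox list (41.0%, 377.5 bases) lies left of its random lists in both panels.

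Midbrain patterning factors were then compared directly with the factors of 2 other regions. Their median breadth of 4020 bases (29 genes) exceeded the 377.5 bases of the 39 Hox genes by 3642 bases (95% bootstrap interval 2424 to 6709), with an adjusted p of 2e-05 in a two-sided permutation test whose raw p of 1e-05 is the smallest that 100000 permutations can give. The test treats genes as independent units, but some neighbouring Hox genes had the same covered bases, such as Hoxb3 and Hoxb4 (357.5 each). The p-value and interval may therefore overstate the evidence. The difference from the 20 forebrain factors was 861 bases (95% bootstrap interval -1209 to 4081), and it did not pass the threshold (adjusted p = 0.480, permutation test).

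The broadest domains included those at Zic1 and Zic4, Pou3f3, Nr2f2 and Sox2. When replicated peaks at most 1 kb apart were joined, 31095 domains resulted, with a median width of 1197 bases and 142 wider than 10 kb. The widest spanned 34325 bases on chromosome 9, positions 91350245 to 91384569, and contained the TSSs of Zic1 and Zic4, zinc-finger factors of the dorsal neural tube. It joined 18 peaks, which covered 28160 ± 684 bases (SD, n = 2) of it in the single replicates. The next domain, 33412 bases on chromosome 13 (positions 83712878 to 83746289), held no protein-coding TSS but that of the microRNA gene Mir9-2. The others contained Pou3f3 (31576 bases), Nr2f2 (29417 bases), Sox2 (29407 bases), Zfhx3 (29097 bases), Bcl11a together with A830031A19Rik (27802 bases), Meis2 (27478 bases), Nr2f1 (24595 bases) and Ebf3 (23867 bases). Thus 9 of the 10 domains contained a protein-coding TSS. Of these 10 regions, 9 overlapped one of the 10 broadest domains of replicate 2 alone and 8 one of those of replicate 1 alone. Only 2 did so when peaks were not joined across gaps.

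**Figure D4:**
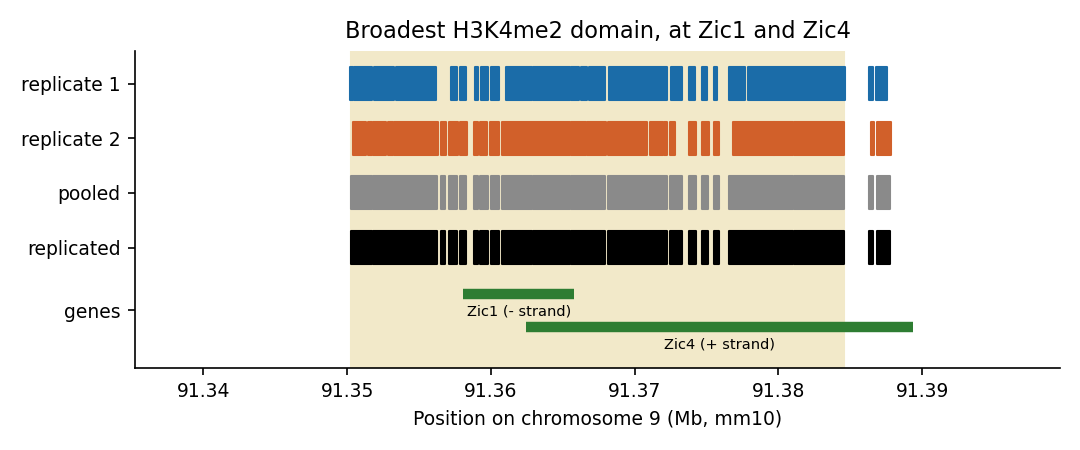
Peaks of replicate 1, replicate 2, the pooled list and the replicated list along chromosome 9 (x axis, Mb, mm10) at Zic1 and Zic4, whose gene bodies are drawn in green. The shaded domain of 34325 bases is filled by 18 replicated peaks with gaps of at most 1 kb.

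Around the TSS, summits lay more often downstream than upstream. Of 15880 replicated summits within 1 kb of a protein-coding TSS, 64.9% were downstream (exact binomial 95% interval 64.2 to 65.7, which covers counting error only). In the single replicates the share was 63.5% ± 2.20 (SD, n = 2). The fullest bin was 500 to 600 bases downstream in both replicates, with 1468 and 1409 summits. On the upstream side, the fullest bin was 200 to 300 bases from the TSS in both replicates. A further local maximum lay 100 to 200 bases downstream, with 1210 and 1161 summits. The lowest bin between the upstream and the main maximum was 0 to 100 bases upstream in replicate 1 (791 summits). In replicate 2 it was 100 to 200 bases upstream (731 summits).

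**Figure D5:**
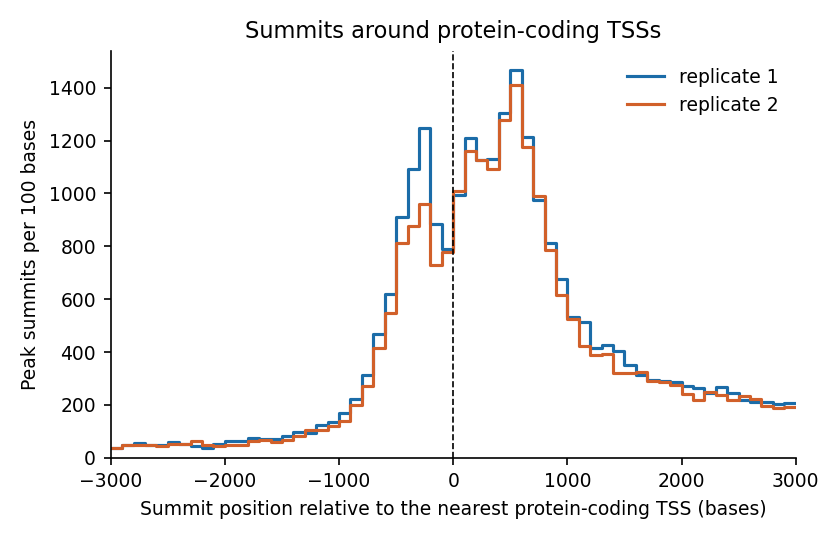
Peak summits per 100 bases (y axis) by position relative to the nearest protein-coding TSS (x axis, bases, positive downstream) in replicate 1 (blue) and replicate 2 (orange). Both curves have their maximum at 500 to 600 bases downstream and a dip just upstream of the TSS, which the dashed line marks.

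Peak density differed between chromosomes by more than between replicates. Chromosome 11 had the highest density, 31.4 ± 0.0476 peaks per Mb, followed by chromosome 19 with 28.8 ± 0.413, whereas chromosome 14 had the lowest among the autosomes with 15.7 ± 0.140 (SD, n = 2). The X chromosome had 8.70 ± 0.00433 peaks per Mb and the Y chromosome 0.108 ± 0.00802. The density of X was 0.412 ± 0.00222 times that of the autosomes, while its density of protein-coding genes was 0.668 times theirs. On X, 50.9% of 948 protein-coding genes had a replicated promoter peak, compared with 65.7% of all protein-coding genes.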

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

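Peaks outside the 21 chromosomes were the only item flagged in data that no comparison used. Each replicate had 19 peaks on unlocalized and unplaced scaffolds. This passed the flagging limit of 3, which a count of 0 allows, but that limit does not test whether the peaks are signal. In replicate 1, 8 of them, and in replicate 2, 9 lay on a single unlocalized scaffold of the X chromosome, with enrichments of up to 11.7 and 13.7.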

How the results depend on the processing

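All 6 calls of lists above and 7 of lists below other genes in promoter occupancy were kept with the pooled list and with an enrichment of at least 4, and the CpG odds ratio stayed between 124 and 154. The broad lists and the difference from Hox genes held with either replicate alone. The effect of read depth could not be examined, since the lists hold no counts.

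Shared peaks of replicate 1 and of replicate 2 were 87.6% and 75.3% with 1 shared base, 63.5% and 63.1% with 50% reciprocal overlap, 95.3% and 77.4% with an enrichment of at least 4, 98.7% and 91.6% among the 20000 strongest peaks, and 85.5% and 69.3% with a q-value of at most 0.05, a setting chosen after seeing the data. With 1 shared base, 93.0% of replicated peaks were found in both replicates. With an enrichment of at least 4, the rank correlation was 0.906, the promoter share of summits 50.9%, the share of genes with a promoter peak 65.0% and the density of X 0.474 times that of the autosomes. With windows of 500 bases and 2 kb, the promoter share of summits was 27.0% and 51.9%, the share of genes with a promoter peak 65.0% and 66.6%, and the share of summits downstream of the TSS 57.1% and 68.1%. It was 67.8% with 1 summit per TSS. The pooled list had a promoter share of 38.6%. The share of genes with a promoter peak was 64.1% for the outermost TSS and 66.9% for the comprehensive TSS set, the latter chosen after seeing the data. With 1 replicate left out, the promoter share of summits was 36.1% to 38.7%, the share of genes with a promoter peak 65.8% to 66.5% and the share of downstream summits 61.9% to 65.0%. With a breadth window of 2 kb, 4 lists were above the central 95%. Against random lists not matched on CpG content, 6 lists were below it, the added ones being erythroid, liver, epidermal and olfactory receptor genes. Without joining across gaps, 2 of the 10 broadest domains stayed among the 10 broadest. For single lists, genes and peaks, 630 recomputed values stayed the same, 136 moved by more than the spread, 11 lost and 8 gained a call, and no result reversed.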

Other observations

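The gene families below, the loci rich in distal peaks and the tests of CpG content were chosen after the first results were seen. Some families of transcription factors and of neuronal channels and receptors had broad H3K4me2, and others did not. All 5 ZIC, all 6 Iroquois and all 4 nuclear factor I genes had a promoter peak, with median breadths of 8136, 7862 and 7217 bases, each at the 100th percentile of CpG-matched random lists. By promoter count, the highest possible in each, these families were at percentiles 61.3, 54.6 and 50.9. Zic1 and Zic4 lie in the same broad domain, so the members of a family are not all separate loci. The 19 SOX genes had a median of 5451 bases (percentile 100), led by Sox2, Sox1, Sox12 and Sox11, and the 17 ionotropic glutamate receptor genes, all with a promoter peak, had 5047 bases (percentile 100). Ephrins and Eph receptors, which guide axons, had a peak at 22 of 22 promoters with a median of 4550 bases (percentile 100), and voltage-gated potassium channels at 16 of 17 with 4183 bases (percentile 100). The LIM-homeodomain, forkhead, NK homeodomain and T-box factors were at percentiles 76.4, 59.5, 41.4 and 4.14 for breadth, and nicotinic receptor subunits at 72.9. Ribosomal protein genes had a peak at 73 of 76 promoters and a median of 2603 bases (percentile 46.1), and proteasome subunits at 38 of 39 with 1909 bases (percentile 0.35). Vomeronasal receptors had a peak at 1 of 327 promoters and beta-defensins at 0 of 42. Clustered protocadherins, cell-surface proteins each with its own promoter, had a peak at 18 of 57 and a median of 92.5 bases (percentile 0). The 5 C-type members (Pcdhac1, Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5) all had one, with a median breadth of 5514 bases, compared with 1 of 12 other alpha, 3 of 22 beta and 9 of 18 other gamma members. With replicate 2 alone these counts were 3 alpha, 3 beta and 13 gamma members. The difference between the C-type and other members was not tested.

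Some loci had more distal peaks than random placements gave; they were picked for their high counts and do not describe distal peaks as a whole. Zfhx3 was the nearest protein-coding gene of 45 replicated peaks more than 5 kb from any TSS, against a highest count of 17 in 100 random placements. In the lists of replicate 1 and replicate 2 its count was 61 and 80. Tcf7l2, a WNT pathway factor, had 32 (random maximum 9), Pbx1 had 26 (12), Meis2 had 24 (10), Bach2 had 22 (7), Bcor had 21 (4) and Efna5 had 35 (25). In contrast, Tenm3 with 26 and Celf4 with 23 stayed within the random range, whose maxima were 34 and 27. The median over 6000 genes with any such peak was 2. Among the loci named so far, the median enrichment of the distal peaks ran from 3.64 (Bach2) to 9.45 (Bcor) and was 4.01 at Zfhx3. Random placements moved each peak separately, while the peaks of a broad domain lie together. The random maxima may therefore be too low. Th, the rate-limiting enzyme of dopamine synthesis, had no promoter peak and no covered base within 5 kb of a basic-set TSS in either replicate. Pitx3, Slc6a3 and Slc18a2, also markers of dopaminergic neurons, had 3155 ± 26.9, 1321 ± 47.4 and 2202 ± 41.0 covered bases (SD, n = 2). The peaks were called on tissue pools and cannot be assigned to a cell type. A missing peak therefore does not show that Th lacked the mark in dopaminergic neurons. These 4 genes were chosen after their values were seen.

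Few Hox promoters carried a peak, and promoter CpG content argued against itself as the cause. The Hox count stood at percentile 0 of CpG-matched random lists, which had a mean of 91.2% of genes with a peak, and at percentile 0 also with replicate 1, replicate 2 or a window of 2 kb. For the Hox promoters that did have a peak, hindbrain tissue carried over in the dissection was a candidate source. It predicts peaks at paralog groups 1 to 5. These had them at 8 of 15 promoters against 8 of 24 for groups 6 to 13 (Fisher's exact p = 0.318, two-sided), so this stays open. Within groups 1 to 5, Hoxa2, Hoxb1, Hoxb2 and Hoxb5 had no covered base within 5 kb in either replicate. Hoxa3, Hoxb3 and Hoxc4 had no replicated promoter peak. The test pooled these groups and cannot separate their members, and that source does not predict the 8 peaks in groups 6 to 13. Group 13, which is used at the posterior end of the body, had a peak at 4 of 4 promoters, with enrichments of 5.15 to 7.30. The highest Hox promoter enrichments were those of Hoxa1 (28.5) and Hoxd1 (24.6) in group 1, where Hoxb1 had no peak. No biological explanation was tested, since the design has 1 group.

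CpG content was weighed in the same way for the other lists with few promoter peaks. The germline list (16.7%, with 64.3% in matched lists) and the olfactory receptors (0.352%, with 7.57%) were at percentile 0 with each list and window tried, so low CpG content alone does not account for them. Microglial and epidermal genes were at percentiles 10.4 and 8.6, within the range that CpG content gives, so their low counts may follow from it. Muscle and liver genes were at percentiles 1.31 and 1.94, but muscle reached 16.9 with replicate 2 and liver 6.27 with a window of 2 kb, which leaves the explanation open for both. The requirement that every list and window agree was added after the values were seen.

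Of replicate 2 peaks, 31.1% were not found in replicate 1, against 15.6% in the other direction. This difference depends on the overlap rule. With 50% reciprocal overlap, 63.5% of replicate 1 peaks and 63.1% of replicate 2 peaks were found. With 1 shared base the shares found were 87.6% and 75.3%. Weak peaks near the calling threshold are a candidate explanation that met its test, since 0.0536% of the strongest 25% of replicate 2 peaks were not found (exact binomial upper bound 0.110%). The test places the unfound peaks among the weaker ones but cannot tell why they were weak. Nor can it account for the difference between the directions, since the share was 0% for the strongest 25% of replicate 1 peaks. Weak peaks may not account for all of the unfound replicate 2 peaks, as 44.8% of the second-lowest 25% (enrichment 3.78 to 6.90) were also not found, against 14.3% for replicate 1. These shares by enrichment were computed only with the main overlap rule, so this gap may depend on it too. Different cell types in the pools, another candidate, stay open: of 320 listed marker genes, 14 (4.375%, exact binomial 95% interval 2.41 to 7.23) had a promoter peak in one replicate only (12 of them in replicate 2, among these Hoxb9, Hoxc4, Hoxc8, Hoxc9 and Hoxc10), a value below the 5% set in advance but with an interval that includes it. The requirement on the interval was added after the value was seen, and without it the rule set in advance would count this explanation as excluded. That rule could not exclude it, because the 320 genes were not all specific to a cell type. They included the housekeeping, pan-neuronal, neural progenitor and immediate-early and stress lists, with a peak at every promoter in both replicates. Over all protein-coding genes, 1.35% had a promoter peak in one replicate only, below the interval of 2.41 to 7.23.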
